A study of Homo sapiens with 2 samples.

How the data were processed

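RNA from 2 cultures of Huh-7 cells, a human hepatoma cell line, was measured on an Affymetrix expression array, with 1 array per condition. Per the labels' protocols, biotinylated cRNA was made from 6 µg of total RNA. The treated culture received recombinant interferon-alpha 2b at 100 U/mL for 6 hours, starting 24 hours into incubation, and the untreated culture had its medium changed. The harvest time of the untreated culture was not given in the sources used here. Per the submitters' processing notes, the arrays were processed with GCOS, Affymetrix's scanner software. Its version, the background correction, the summary of probes into probe sets and the scaling between arrays are not given in the sources used here.

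The deposited values are intensities on a linear scale, 1 per probe set and array, as the authors made them. The table holds 54675 probe sets, of which 62 are control probe sets. Intensities ran from 5.63 to 15261.5 on the untreated array and from 5.74 to 17215.6 on the interferon array. The medians of the other 54613 probe sets were 48.84 and 48.04. After removal of the lowest and highest 2% of values, the means were 159.2 and 166.84, so the arrays had not been brought to a common trimmed mean. No detection calls or scanner files were used here. The RT-PCR measurements that the design text mentions were not analysed here.

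Probe sets were named from the platform annotation. Of the probe sets other than controls, 41091 had 1 gene, 1801 had several genes and 11721 had no gene named in that table, which does not mean that they have none. Symbols of 41037 probe sets were brought up to date through the gene ID. Probe sets with several genes or no named gene entered no gene-level result. Some genes are therefore not reported here. No coordinates are given, because no genome build is attached to the values.

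A floor was set at the 50th percentile of all values of both arrays together, controls left out, which was an intensity of 48.46. Values below it were raised to it before the log2 was taken. For each gene the probe set with the highest mean log2 intensity over both arrays was used. Its change was not a criterion. The mean includes the interferon array, however, so a probe set that rises gains rank and one that falls loses it. The choice of 1 probe set per gene left 19775 genes, of which 13269 were above the floor on at least 1 array with that probe set and were counted. Of the genes below the floor on both arrays, 3 had another probe set above it. The result is the log2 ratio of the interferon array over the untreated array. Where the untreated value was below the floor, the fold is a lower bound and is given as "at least". Genes at least 2-fold higher or lower were counted. With 1 array per condition the comparison has no replicate check, no test can be made and no p-value is given. The number of arrays limits the precision.

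Spreads within the arrays were used for scale, and neither of the following is a replicate error. Among the 12742 genes above the floor on both arrays, the central 95% of log2 ratios lay between -0.29 and 0.30, with a robust SD (scaled median absolute deviation) of 0.13. Some of these genes had the same value on both arrays to the precision kept here, among them PIAS1 (436.558), ATF6 (305.15) and FOSB (69.671). How such ties arose is not known, and each enters the spread as a log2 ratio of 0. In 5912 genes with several probe sets above the floor on both arrays, the median range of the log2 ratio between probe sets of the same gene was 0.14.

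The named genes follow a rule set before the data were examined. They are the 20 highest ratios and 10 lowest ratios among genes above the floor on both arrays, the 10 highest bounds among genes below the floor on the untreated array, the 5 lowest bounds among genes below it on the interferon array, and members of the fixed gene lists as examples. A probe set of the same gene was called discordant if it lay on the other side of 0 by 0.5 or more. The 34 gene lists, with 565 different members of which 498 had a named probe set, were also fixed in advance. For each list with at least 3 counted genes, the median log2 ratio was set against the medians of 10000 random lists of the same size, matched on mean log2 intensity in 20 bins. The percentile describes these 2 arrays and is not a test of the treatment.

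The procedure was tested on simulated data made from the mean of the real arrays with the measured spread. For this comparison, over 13183 counted genes, the 2-fold threshold called 48 of 50 genes changed 2.5-fold, 50 of 50 changed 3-fold, 50 of 50 changed 4-fold and 0 of 50 changed 1.5-fold. It called 0 of the 12983 unchanged genes. The changed genes were drawn only from those with untreated intensities at least 4 times the floor. Recovery of genes nearer the floor or below it was therefore not tested. The simulated noise was normal with the same SD for all genes, so the count of 0 followed from that choice. Of 100 random simulated lists, 4 fell outside the central 95% of their matched lists. Alternatives set in advance were floors at the 40th, 65th and 75th percentile, pseudocounts of 32 and of 1 in place of a floor, median, quantile and lowess scaling, the median over probe sets of a gene, removal of probe sets whose identifiers end in _x_at or _s_at, and thresholds of 1.5-fold and 3-fold. Alternatives chosen after seeing the data were a floor at the highest value of the TrpnX control probe sets (17.16) and centring on the hybridisation controls. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 (lowess) and matplotlib 3.10.9 were used.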

Results

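Gene expression was compared between 1 culture of Huh-7 cells treated with interferon-alpha at 100 U/mL for 6 hours and 1 untreated culture, with 1 array each. The question was which transcripts of this hepatoma line differ after exposure to interferon-alpha. On the untreated array 50.19% of the probe sets lay above the floor of 48.46, and 49.81% did on the interferon array. All values below come from these 2 arrays, and no difference has a replicate check.

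With the deposited scaling the difference between the arrays was one-sided. Of 13269 counted genes, 57 (0.43%) were at least 2-fold higher on the interferon array and 0 were at least 2-fold lower. Median, quantile and lowess scaling also gave 0 lower, whereas centring on the hybridisation controls, chosen after seeing the data, gave 44 higher and 13 lower. Among the 57, 41 were above the floor on both arrays and 16 were below it on the untreated array. The ratio was at least 4-fold in 29 genes and at least 8-fold in 16. Of the 57 genes, 42 belonged to the 9 lists of interferon-related genes fixed in advance. At a threshold of 1.5-fold, 100 genes were higher and 11 lower. Across the genes above the floor on both arrays the median log2 ratio was 0.04, and log2 intensities correlated at r = 0.993 across genes, which are not independent replicates.

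**Figure D1:**
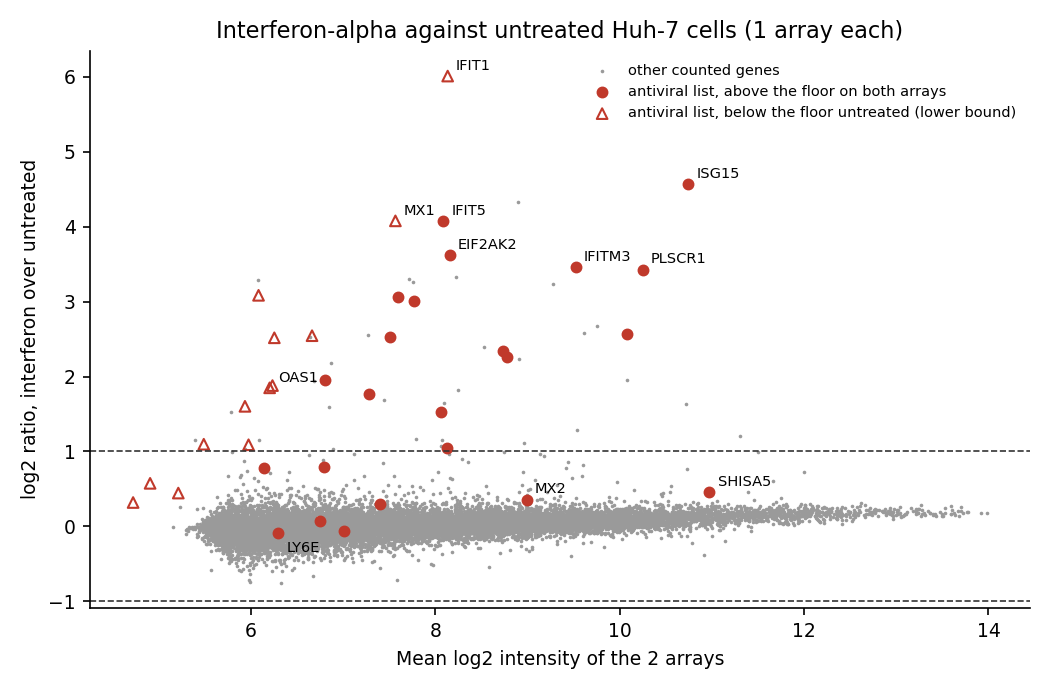
Each point is a counted gene, with the mean log2 intensity of the 2 arrays on the horizontal axis and the log2 ratio of interferon over untreated on the vertical axis; red marks the antiviral list, open triangles are lower bounds, and dashed lines mark 2-fold. The 57 genes at least 2-fold higher lie above the upper line and no gene lies below the lower one.

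The highest ratios belonged to antiviral effectors and to the machinery of the interferon response itself. ISG15, a ubiquitin-like protein that is conjugated to other proteins, had intensities of 351.2 untreated and 8332 with interferon, a ratio of 23.7-fold (log2 4.57). IRF9, the DNA-binding subunit of the transcription factor complex that type I interferon activates, had 106.7 and 2143, or 20.1-fold (log2 4.33). IFIT1, a protein that binds viral RNA lacking the host's cap methylation, was below the floor on the untreated array at 25.3 and had 3125 on the interferon array, which is at least 64.5-fold higher. MX1, a dynamin-like GTPase that restricts influenza and other viruses, had 44.0, below the floor, and 818.2, at least 16.9-fold higher. IFIT5 was 16.9-fold higher, and both of its counted probe sets exceeded 2-fold, with log2 ratios of 2.48 and 4.08.

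The remaining genes among the 20 highest measured ratios lay between 4.79-fold and 12.3-fold. EIF2AK2, the kinase PKR that halts translation on double-stranded RNA, was 12.3-fold higher on its chosen probe set. Of its 3 counted probe sets 2 exceeded 2-fold, and the lowest had a log2 ratio of 0.38. The membrane proteins IFITM3 (11.03-fold) and IFITM2 (4.79-fold), which block entry of enveloped viruses, were read by probe sets that can cross-hybridise with the neighbouring family members, so their separate values are uncertain. The scramblase PLSCR1 was 10.7-fold higher and the helicase HELZ2 10.0-fold higher, the latter in 2 of 4 counted probe sets. IFI6 was 8.34-fold and SP110 8.06-fold higher. Next came TRIM25 (6.39-fold), USP18 (5.96-fold), ZC3HAV1 (5.92-fold), RIGI (5.90-fold), IFIT3 (5.79-fold) and HERC5 (5.07-fold). Besides IFIT1 and MX1, the highest bounds were those of IFIH1 (at least 9.74-fold), CMPK2 (8.48), OAS3 (5.84), APOL6 (5.74), EPSTI1 (5.72), HERC6 (3.68), OAS1 (3.60) and IFITM1 (3.04). In none of the 57 genes did another counted probe set lie on the other side of 0 by 0.5 or more. Of the 26 with several counted probe sets, 12 exceeded 2-fold in every one. Among the rest were PML (1 of 8 probe sets past 2-fold, the lowest at a log2 ratio of -0.40), SP110 (4 of 5), ZC3HAV1 (2 of 3), APOL6 (2 of 3) and EPSTI1 (1 of 2).

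**Figure D2:**
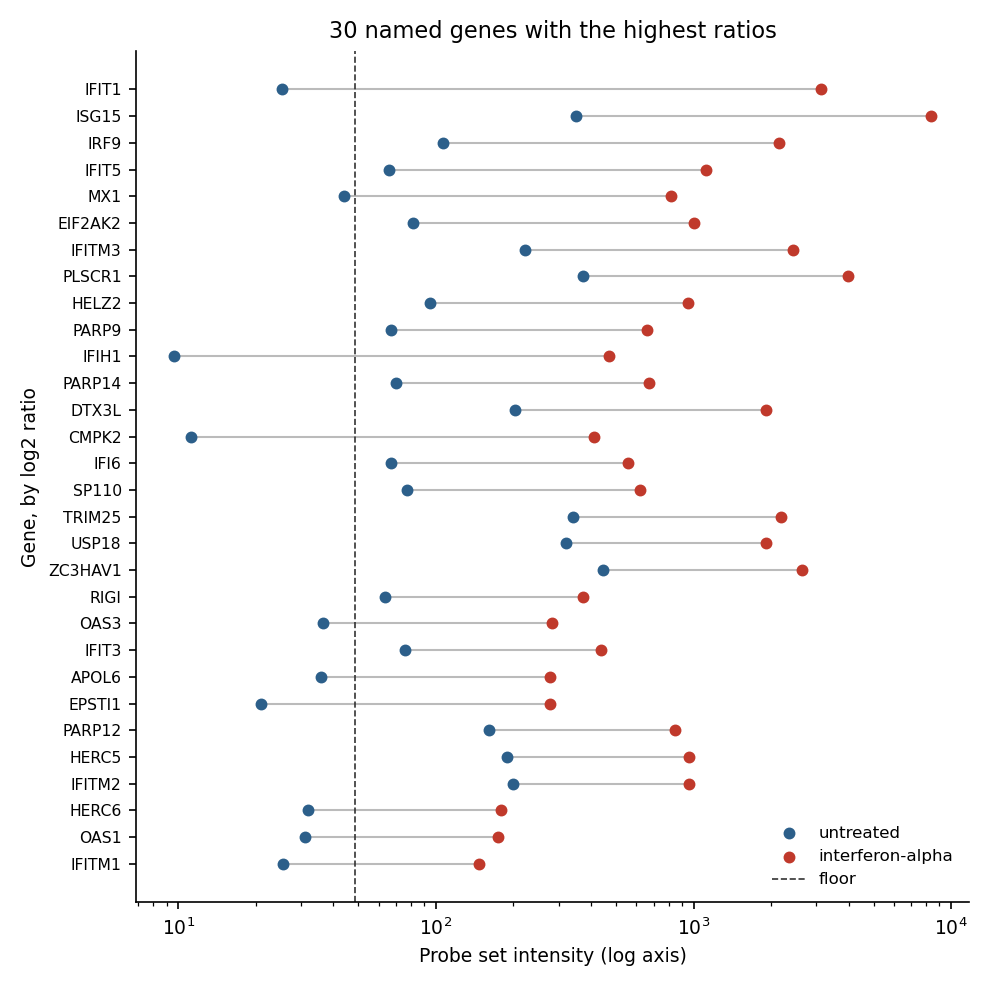
Probe set intensity on a log axis for the 30 named genes with the highest ratios, 1 row per gene, untreated in blue and interferon-alpha in red, with 1 array each; the dashed line is the floor of 48.46. Intensities of ISG15 lie at 351.2 and 8332, and those of IFIT1 at 25.3 and 3125.

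In the list of antiviral interferon-stimulated genes, 25 of the 36 counted members were at least 2-fold higher, 11 lay between and 0 were at least 2-fold lower. The median log2 ratio was 1.86, whereas the central 95% of matched random lists lay between -0.04 and 0.07. The 11 members under 2-fold included OASL (1.72-fold), the tetherin gene BST2 (1.72-fold), MX2 (1.28-fold), the exonuclease gene ISG20 (1.23-fold), APOBEC3F (1.05-fold) and LY6E (log2 -0.09). RSAD2, DDX60 and IFI44L were below the floor on the untreated array and barely above it with interferon, at 65.9, 72.1 and 60.4, so that their bounds were 1.36-fold, 1.49-fold and 1.25-fold. A further 8 members were below the floor on both arrays with the probe set used, although another probe set of XAF1 was above it with a log2 ratio of 0.07. Among the 8 were IFI27 at 25.1 and 34.5, IFI44 at 10.8 and 11.3, and TRIM22 at 8.50 and 13.2. The median of this list varied with the floor, and it was 1.10 without probe sets ending in _x_at or _s_at.

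In the list of PARP, SLFN and GBP families, the members past 2-fold were PARP genes and a partner. PARP9 (9.86-fold), PARP14 (9.61-fold), PARP12 (5.27-fold), ZC3HAV1 and the PARP9 partner DTX3L (9.40-fold) made up the 5 of 8 counted members that were at least 2-fold higher. PARP10 was 1.37-fold (lowest of 4 probe sets at log2 0.02), GBP2 1.27-fold and SLFN5 at least 1.09-fold higher. The other GBP members (GBP1, GBP3, GBP4 and GBP5) and SLFN11, SLFN12 and SLFN13 were below the floor on both arrays. The list's median was 2.48, against a central 95% of -0.07 to 0.12 for matched random lists. It was 1.43 with the floor at the 40th percentile and 0.38 with a pseudocount of 1 over all genes, settings that count members below the floor.

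Genes of ISG15 conjugation were higher in 6 of 7 counted members, with a median log2 ratio of 2.34. These were ISG15 itself, the E2 enzyme UBE2L6 (3.87-fold), HERC5, HERC6 and TRIM25, which are ligases, and the ISG15-specific protease USP18. ARIH1 had a ratio of 1.01-fold. Of 15 counted genes for nucleic acid sensing, 5 were at least 2-fold higher: the cytosolic RNA sensors IFIH1 (MDA5) and RIGI, the RIG-I ligase TRIM25, the adaptor MYD88 (2.43-fold) and ZNFX1 (2.23-fold). The adaptor MAVS had a log2 ratio of -0.02, TBK1 0.07, IRF3 0.13 and STING1 -0.29. DHX58 had a log2 ratio of 0.04 at intensities of 53.3 and 54.8, close to the floor, and TLR3 was below the floor on both arrays.

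Components that receive and transmit the interferon signal showed little difference apart from IRF9. Among 10 counted genes of the receptor and JAK-STAT list, IRF9 was the only one at least 2-fold higher, and the other 9 lay between -0.11 and 0.26 on the log2 scale. These included the receptor chains IFNAR1 (-0.10) and IFNAR2 (-0.11) and the kinases JAK1 (0.12) and TYK2 (0.01), and the list's median of 0.08 was at the 86.91th percentile of matched random lists. Among transcription factors and partners, 3 of 10 counted genes were at least 2-fold higher, namely IRF9, BATF2 (3.85-fold) and NMI (2.82-fold). IRF1 was 1.85-fold higher, and IRF7 was below the floor on both arrays at 41.1 and 39.8. In the list of negative regulators, 2 of 14 counted genes were at least 2-fold higher, USP18 and UBE2L6. UBE2L6 was a member of that fixed list, but it is the E2 enzyme of ISG15 conjugation named above. The suppressors of cytokine signalling SOCS1 (0.17) and SOCS3 (-0.07) and the phosphatases PTPN6 (0.13) and PTPN1 (-0.09) had log2 ratios within the central 95% of all genes on the probe sets used, but the counted probe sets of SOCS1 ran from 0.09 to 0.65.

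For antigen presentation by MHC class I, 3 of 16 counted genes were at least 2-fold higher. These were the peptide transporter subunits TAP1 (3.02-fold) and TAP2 (2.04-fold) and HLA-E (2.11-fold, in 1 of 3 counted probe sets). HLA-C was 1.79-fold higher (its 4 counted probe sets ran from log2 0.10 to 0.84), B2M 1.66-fold, TAPBP 1.54-fold and the proteasome activator PSME1 1.51-fold, while HLA-G and HLA-B were 1.27-fold and 1.23-fold higher. HLA genes share sequence, and their separate values are uncertain. The immunoproteasome subunits PSMB8 and PSMB9 were below the floor on both arrays, and PSMB10 had a log2 ratio of 0.09. The 13 counted genes of the constitutive proteasome core had a median of 0.17 (-0.002 after lowess scaling) and lay within the matched range. Of the MHC class II list, 8 of 10 members were below the floor on both arrays, and the counted members HLA-DMB and CD74 had log2 ratios of 0.01 and -0.12.

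Cytokine and cell death genes differed by 2-fold in few members. Of 10 counted chemokines and cytokines, the death ligand gene TNFSF10 (TRAIL) was at least 2.21-fold higher, the only one past 2-fold with the floor used. CXCL10, a chemokine that type I interferon induces in many cell types, had intensities of 24.4, below the floor, and 57.8. It was at least 1.19-fold higher, a bound that the floor limits. CXCL1 was 1.43-fold and CCL20 1.38-fold higher, and IL1B had a log2 ratio of -0.43 near the floor. IFNB1, IFNL1, IL6, TNF, CXCL9 and CXCL11 were below the floor on both arrays. Of 15 counted apoptosis genes only TNFSF10 exceeded 2-fold, followed by CASP8 (1.94-fold, with its lowest probe set at a log2 ratio of 0.32).

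Lists with few members past 2-fold had small median log2 ratios, of 0.36 for transcription factors and partners, 0.15 for negative regulators, 0.13 for nucleic acid sensing, 0.32 for class I presentation, 0.14 for chemokines and cytokines, 0.15 for apoptosis, 0.18 for immediate early and NF-kB target genes and 0.10 for p53 targets. With the floor and scaling used, all 8 lay above the central 95% of matched random lists, the lowest being p53 targets at the 97.51th percentile. After centring on the hybridisation controls all 8 were below 0. Their place above the median of all genes was unchanged there, because a constant shift cannot alter it. Over the other alternatives the medians ran from 0.18 to 0.69 for transcription factors and partners, from 0.09 to 1.18 for nucleic acid sensing, from 0.17 to 0.33 for class I presentation and from 0.01 to 0.17 for chemokines and cytokines. They ran from 0.07 to 0.15 for negative regulators, from 0.03 to 0.18 for apoptosis, from 0.04 to 0.18 for immediate early and NF-kB target genes and from 0.04 to 0.11 for p53 targets. Among p53 targets and among immediate early and NF-kB target genes, none was at least 2-fold changed.

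**Figure D3:**
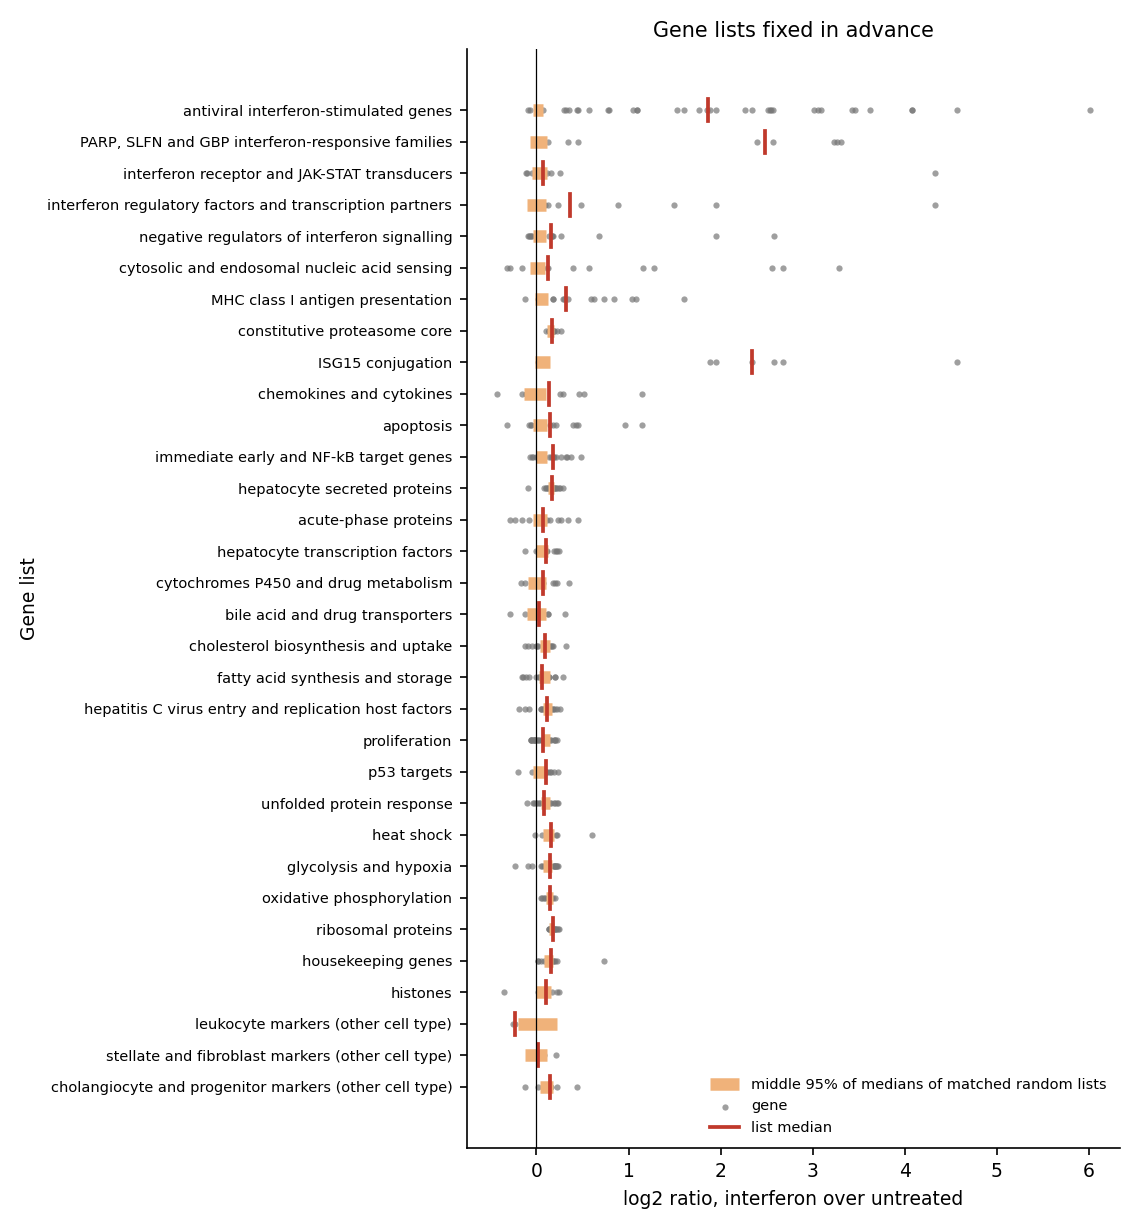
Log2 ratio of interferon over untreated for the counted members of each fixed gene list with at least 3 of them; grey points are genes, red lines are list medians and orange bars span the central 95% of medians of 10000 matched random lists. The antiviral, PARP/SLFN/GBP and ISG15 conjugation lists have medians of 1.86, 2.48 and 2.34, while the liver, metabolic and proliferation lists lie between 0.02 and 0.18, with signs that depend on the scaling.

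Liver, metabolic and growth programmes held no gene at least 2-fold changed, and 24 of the 34 lists were without one. Median log2 ratios were 0.17 for hepatocyte secreted proteins (ALB 0.26 but -0.37 on its lowest probe set, APOB 0.29, APOC3 -0.09), 0.10 for hepatocyte transcription factors, 0.07 for acute-phase proteins, 0.07 for cytochromes P450 and drug metabolism and 0.02 for bile acid and drug transporters. They were 0.10 for cholesterol biosynthesis and uptake, 0.06 for fatty acid synthesis and storage and 0.12 for host factors of hepatitis C virus entry and replication, in which CD81 had 0.05, SCARB1 0.08, CLDN1 0.20 and OCLN 0.18. Proliferation genes had a median of 0.07, at the 2.80th percentile of matched lists, the unfolded protein response 0.08, heat shock 0.16, glycolysis and hypoxia 0.15, oxidative phosphorylation 0.14, ribosomal proteins 0.18, housekeeping genes 0.16 and histones 0.10. These medians lay within the central 95% of lists of genes of like brightness. Their signs depended on the scaling, since all were below 0 after centring on the hybridisation controls and several after quantile or lowess scaling, among them proliferation (-0.07 and -0.06), fatty acid synthesis (-0.06 and -0.05) and ribosomal proteins (-0.003 and -0.03). EGFR and GATA6, and PSMB2 of the proteasome list, each had another probe set on the other side of 0 by 0.5 or more.

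Markers of other liver cell types were below the floor on both arrays or did not differ by 2-fold, and some were bright on both. Of 7 leukocyte markers with a probe set, 4 were below the floor on both arrays, including PTPRC and CD3E. The 3 counted ones were LYZ (log2 0.14), CD79A (-0.24) and CD14 (-0.25), with a median at the 1.38th percentile of matched lists. Of 8 endothelial markers 6 were below the floor on both arrays, and the counted ones, PECAM1 and VWF, had log2 ratios of -0.05 and -0.42. The stellate and fibroblast list had a median log2 ratio of 0.02 and the cholangiocyte and progenitor list 0.15, with EPCAM at 0.14 and SOX9, its highest member, at 0.44. Of 7 cholangiocyte and progenitor markers only 1 was below the floor on both arrays, and the counted members had a median untreated intensity of 1259.8. For stellate and fibroblast markers 3 of 9 were below the floor, and that median was 108.5. LYZ had intensities of 2064 and 2271.

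With the floor and scaling used, no gene reached a 2-fold lower value. The lowest ratio above the floor on both arrays was that of MCTP2, with intensities of 104.0 and 61.8, or 1.68-fold lower. TCP11L2 was 1.65-fold and PADI4 1.64-fold lower, and the lowest 10 measured ratios lay between -0.75 and -0.58 on the log2 scale. All 10 had untreated intensities between 77.6 and 246.1. MCTP2, TCP11L2 and PADI4 had 5, 7 and 3 probe sets, of which only 1 each was counted, so their values rest on 1 probe set. CROCC, also among the 10, had 3 counted probe sets, with log2 ratios from -0.60 to 0.03. When the genes above the floor on both arrays were split by brightness into 10 equal groups, the central 95% of log2 ratios ran from -0.37 to 0.27 in the dimmest group and from -0.02 to 0.29 in the brightest. Of the genes below the floor on the interferon array, C11orf16 was at least 1.52-fold and SAMD15 at least 1.49-fold lower, and SAMD15 passed 2-fold (log2 -1.18) with the floor at the 40th percentile. Centring on the hybridisation controls in place of the deposited scaling subtracted 0.43 from every log2 ratio. It moved the median of the genes above the floor on both arrays from 0.04 to -0.39, with 44 genes at least 2-fold higher and 13 at least 2-fold lower, and any ratio above 0 but below that size changed sign.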

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

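The tests of explanations in this part were chosen after the results were seen, as were the lower floor and the centring on the hybridisation controls, whereas the pseudocounts and the median, quantile and lowess scalings had been set before.

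Among the 3079 counted probe sets with no gene named in the annotation used, 14 were at least 2-fold higher with interferon and 0 were at least 2-fold lower, and among 1156 counted probe sets with several genes 2 were at least 2-fold higher. They are singled out because they lie outside the gene-level comparison. The 18 probe sets for the bacterial and phage hybridisation controls (bioB, bioC, bioD and cre) were all brighter on the interferon array, with a median log2 ratio of 0.427 and a range of 0.14 to 0.56. Genes as bright as these controls had a median log2 ratio of 0.01, and the 6 probe sets of the poly-A control dap were also all brighter on the interferon array, with a median of 0.20. Of the 3 TrpnX control probe sets, with untreated intensities of only 8.1 to 17.2, 2 were brighter, with log2 ratios from -0.10 to 0.26.

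A first pattern is the small excess in abundant gene lists, with medians of 0.18 for ribosomal proteins and 0.17 for hepatocyte secreted proteins and for the constitutive proteasome. The median log2 ratio was 0.14 in the brightest of 10 equal groups of genes and -0.04 in the dimmest, a difference of 0.186, which argues against a single scaling factor. The 3 lists did not stand apart from other genes of like brightness, with the farthest median at the 86.35th percentile of matched random lists, so a trend with brightness between the arrays may account for the excess. A rise of abundant transcripts as a class in treated cells would look alike on 1 array per condition and stays open as untested.

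A second pattern is that 0 genes were at least 2-fold lower beside 57 higher. The floor hid 1 such gene, SAMD15. With no floor and a pseudocount of 1, the count was 1 lower against 64 higher, which argues against the floor as the reason for the one-sided result. A scaling offset between the arrays cannot be told apart from a real lack of 2-fold falls. Median, quantile and lowess scaling each gave 0 lower genes, with lowest log2 ratios of -0.79, -0.75 and -0.74. Centring on the hybridisation controls gave 13 lower against 44 higher, but it subtracts a constant from every ratio and decides nothing, and which reference is right is not known from these files. A treatment of 6 hours may be too short for stable transcripts to fall 2-fold, which no value here tests.

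Another pattern is that 11 counted antiviral genes stayed under 2-fold. For RSAD2, DDX60 and IFI44L, which were below the floor in untreated cells, the floor is a likely reason: all 3 exceeded 2-fold when it was lowered to the highest TrpnX control value, with log2 ratios of 1.66 for RSAD2 and of at least 2.07 and 1.82 for DDX60 and IFI44L, which were below that floor too. The other 8 were above the floor on both arrays, so it did not enter their ratios. For OASL, ISG20 and APOBEC3F another counted probe set was at hand and the highest log2 ratio of any was 0.863, which argues against the choice of probe set. For the other 5 (MX2, BST2, APOBEC3G, LY6E and SHISA5) there was no other counted probe set and that explanation stays open, as does a weaker response of these genes in this cell line at 6 hours.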

How the results depend on the processing

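The floor at the highest TrpnX value and the centring on the hybridisation controls were chosen after seeing the data. No paired analysis was possible because each group holds 1 array, and no replicate could be left out. The 57 genes at least 2-fold higher numbered 38 to 64 under the other settings at that threshold. All 57 were among those called with floors at the 40th percentile and at the highest TrpnX value, with a pseudocount of 1 and with lowess centring. The count fell to 38 with a floor at the 75th percentile and to 38 without probe sets ending in _x_at or _s_at, where fewer genes were counted, and it was 100 at 1.5-fold and 41 at 3-fold. With the median over probe sets of a gene, which does not favour the brightest one, it was 52, with 0 genes at least 2-fold lower. The count of genes at least 2-fold lower was 1 with the floor at the 40th percentile, 1 with a pseudocount of 1 and 1 with the floor at the highest TrpnX value; each time it was SAMD15, at intensities of 72.4 and 31.2. It was 11 at 1.5-fold and 13 with centring on the hybridisation controls.

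The median of the antiviral list, 1.86, became 2.076, 1.606 and 1.49 with floors at the 40th, 65th and 75th percentile, 2.072 with the floor at the highest TrpnX value, 1.675 and 2.094 with pseudocounts of 32 and 1, 1.602 with the median over probe sets, 1.10 without _x_at and _s_at probe sets and 1.437 with centring on the hybridisation controls; for the probe set choices the cause was not tested. The median of the PARP, SLFN and GBP list, 2.48, became 1.43 with the floor at the 40th percentile and 0.38 with a pseudocount of 1 over all genes. Centring on the hybridisation controls subtracts 0.43 from every log2 ratio and so turned negative 8 small list medians that had lain above matched lists: transcription factors and partners (-0.068), negative regulators (-0.275), nucleic acid sensing (-0.298), class I presentation (-0.107), chemokines and cytokines (-0.291), apoptosis (-0.282), immediate early and NF-kB targets (-0.249) and p53 targets (-0.324). The median of all genes was -0.39 under that setting. All 8 lay above it, which follows from subtracting a constant and is no further check. The 30 named higher genes were at least 2-fold higher in 343 of 351 recomputed values; the other 8, of HERC6, OAS1, IFITM1, OAS3, APOL6 and EPSTI1, came from floors at the 65th or 75th percentile, which lower a bound by construction. Dim genes are limited by signal over background: 6506 genes below the floor on both arrays with the probe set used gave no ratio.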

Other observations

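The genes described first here were chosen after their values were seen. Of the 57 genes at least 2-fold higher with interferon, 14 belonged to no list fixed in advance. Besides HELZ2 and APOL6 these were 3 members of the tripartite motif family, TRIM14 (4.72-fold), TRIM69 (4.55-fold, in 1 of 2 counted probe sets, the other at a log2 ratio of 0.008) and TRIM56 (2.25-fold, in 1 of 2, the other at a log2 ratio of 0.72). SAMHD1, which hydrolyses deoxynucleotides and restricts retroviruses, was 3.52-fold higher, in 4 of 5 counted probe sets. RNF213 was 3.21-fold higher in 5 of 7 counted probe sets, SHFL 3.14-fold in 3 of 3, and the mitochondrial RNA-processing enzyme PNPT1 3.11-fold. The aminopeptidase LAP3 was 2.30-fold and the kinase PRKD2 2.15-fold higher. LAMP3, DDX60L and LGALS3BP, below the floor on the untreated array, were at least 2.89-fold, 2.23-fold and 2.04-fold higher, for DDX60L in 1 of 2 counted probe sets, the other at a log2 ratio of 0.09.

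Immediate early and NF-kB target genes held no member past 2-fold, yet 13 of the 17 counted had a ratio above 0, led by NFKBIZ (1.40-fold), TNFAIP3 (1.29-fold), EGR1 (1.26-fold) and MYC (1.25-fold). Ratios above 0 were also the more common among all genes above the floor on both arrays, whose median log2 ratio was 0.04. The list's median log2 ratio of 0.18 lay above the central 95% of matched random lists, which ran from -0.01 to 0.11. It was 0.10 after lowess centring, 0.04 without probe sets ending in _x_at or _s_at and -0.249 with centring on the hybridisation controls. No matched range is given for these settings. No cause was tested.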
